A study of Mus musculus with 10 samples.

How the data were processed

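Mouse prostate was studied in animals of the genotype PB-Cre4;Pten LoxP/LoxP, in which a probasin-driven Cre recombinase deletes the tumour suppressor Pten in prostate epithelium. The labels divide 10 libraries by castration status and by RNA fraction: 3 of castrate total RNA, 3 of castrate RP RNA, 2 of intact total RNA and 2 of intact RP RNA. RP RNA is read here as ribosome-protected RNA, because the series is described as ribosome profiling. The tissue label is prostate, while the extraction protocol in the labels speaks of cultured cells, and the sources used here do not settle the difference. The replicate numbers come from the sample descriptions. Nothing in the labels says that the libraries come from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

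The deposited values are whole-number read counts for 24421 gene symbols, one file per library, although the files are named as CPM, which stands for counts scaled to a common library total. The totals differ between libraries and low values run through 0, 1, 2 and 3, so the values were treated as raw counts. TopHat2, HTSeq, edgeR and the genome build mm10 are named, without versions or roles, per the submitters' processing notes. Read trimming, removal of ribosomal RNA, strand use, the handling of reads with several matches and the annotation are not given in the sources used here. Genes that overlap another gene or have near-identical copies are therefore uncertain, and short protected fragments make this worse than for total RNA. Symbols were matched to a RefSeq gene table of the GRCm38.p6 assembly, the assembly of mm10: 23204 matched by symbol, 1096 by synonym and 121 did not match. That table gives gene spans only, so positions below are of whole genes.

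Library totals ran from 2830454 to 6920730 counts. Genes with at least 1 CPM in at least 2 of the 10 libraries were tested, which kept 15838. Counts were scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with 1 mean for each of the 4 groups and all libraries in 1 fit. Castrate was compared with intact in total RNA, in ribosome-protected RNA and in translational efficiency, the last as an interaction term (protected over total in castrate, divided by protected over total in intact). Protected RNA was also compared with total RNA within each status. The plan fixed before the data were examined assumed CPM values and named limma for that case, with edgeR if the files held counts. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are TMM-scaled CPM with the SD between libraries. A group with no counts was set to a floor of 3 counts over the group, and such floors cover counting error only.

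A set of 36 gene lists was fixed before the data were examined, and 33 had at least 3 measured genes. Each was tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Every p given below with an estimated correlation is also a Benjamini-Hochberg adjusted p over the lists. No list passed with an estimated correlation in any of the 3 comparisons. The list of genes the study followed (Klf5, Denr and Cacul1) was chosen by the study on these samples, so its direction is not independent evidence.

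Genes were named by a rule fixed before the data were examined. For castrate against intact, it took the 8 largest positive and 8 most negative log2 fold changes past the threshold, with a mean CPM of at least 5 and no overlap between castrate and intact libraries. Where fewer than 3 passed in a direction, it was filled up to 3 by smallest unadjusted p. The rule added up to 4 members per list by smallest adjusted p, of which the text names those of the lists it describes, and always Pten, Ar, Eif4ebp1, Klf5, Denr and Cacul1. For protected against total RNA it took 4 genes in each direction.

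Same-numbered total and protected libraries deviated together from their group means, with correlations across genes of 0.31, 0.20 and 0.46 in castrate and 0.20 in intact, so the numbers were taken to pair libraries within a status. Castrate libraries of unlike number ran from -0.40 to 0.14. With 2 intact libraries the matched 0.20 and unmatched -0.20 mirror each other by construction. Centring on group means also lowers unmatched values, so this support for pairing is limited. The numbers come from the labels. A fit with the pairs as a block was an alternative.

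The tests were tested on simulated counts for 15838 genes with the real means, library sizes and dispersions. Each count was drawn independently, so the simulation held no pairing of libraries, no correlation between genes and no aberrant library. Its recovery and false calls do not cover those features of the data. In the simulated mRNA comparison edgeR recovered 15 of 100 genes changed 2-fold and 78 of 100 changed 4-fold, with 4 false calls. In the simulated protected comparison it recovered 12 of 100 at 2-fold and 69 of 100 at 4-fold, with 4 false calls. In the simulated translational efficiency comparison it recovered 2 of 100 at 2-fold and 34 of 100 at 4-fold, with 2 false calls. With the pairs as a block it recovered 3 of 100 and 34 of 100, with 10 false calls. The alternatives planned were other pseudocounts, filters, scalings and variance models, smaller sets of libraries, the replicate block, DESeq2 1.42.0 and leaving out each library. Limma on log2(CPM + 1), protein-coding genes only, TMM within each fraction, and omission of castrate pair 3 from both fractions were added after seeing the data.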

Results

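Total RNA and ribosome-protected RNA were sequenced from Pten-deleted mouse prostate, from castrate and from intact animals, to follow how loss of androgen changes RNA abundance and translation. Castrate total RNA libraries held 4393356, 6920730 and 2884235 counts, and castrate protected libraries 3603290, 3563702 and 3536107. Intact total RNA libraries held 4042919 and 5318761 counts, and intact protected libraries 2830454 and 3142169. The 10 most abundant genes took between 5.59% and 16.8% of a library's counts. Pten, the deleted gene (chromosome 19, 32757577 to 32826160, mm10), was at 239 ± 18.6 CPM (SD, n = 2) in intact total RNA and 180 ± 31.8 CPM (SD, n = 3) in castrate total RNA. No library without the deletion was analysed here, and a count over the whole gene does not show the deleted part, so this level does not check the genotype. The first principal component held 58.4% of the variance and separated the fractions, and the second held 12.8% and separated castrate from intact libraries.

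**Figure D1:**
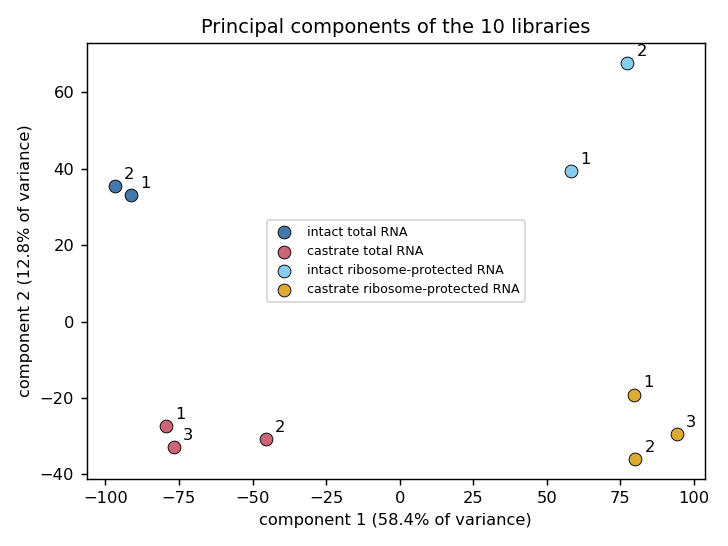
Each point is 1 of the 10 libraries, numbered by replicate, placed by its first component (58.4% of the variance, horizontal) and second component (12.8%, vertical) of log2 CPM. Total RNA libraries lie left of protected ones, castrate libraries lie below intact ones, and castrate total RNA replicate 2 at -45.5 lies nearest to the protected libraries on the first component.

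The first comparison asked how castration changed RNA abundance. Secretory and androgen-regulated genes fell in castrate total RNA. Spink1, a secreted trypsin inhibitor (chromosome 18, 43728069 to 43737237), fell from 250.2 ± 76.3 CPM (SD, n = 2) to 1.14 ± 0.69 CPM (SD, n = 3), a log2 fold change of -7.72 ± 0.50 (SE) with an edgeR adjusted p of 2.78e-05. Fkbp5, a chaperone gene directly induced by steroid receptors (chromosome 17, 28398753 to 28486149), fell from 253 ± 11.3 to 41.6 ± 4.86 CPM, a log2 fold change of -2.60 ± 0.18. The androgen response and prostate secretion list had 16 of 35 measured members lower and 1 higher over all genes tested, and 18 lower and 2 higher adjusted over the list alone. The higher member was Hpgd at 1.60, named after its value was seen. The camera adjusted p of the list was 1.99e-23, and the adjusted p was 0.079 with an estimated correlation.

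Of the 511 genes called by edgeR in castrate total RNA, 50 were also called with total RNA libraries alone, which gave 52 calls. The fit of all 10 libraries took same-numbered total and protected libraries as independent in its estimate of the spread. In that fit 254 genes were higher and 257 lower in castrate total RNA. Among called genes with a mean of at least 5 CPM and no overlap between castrate and intact libraries, the largest falls after Spink1 were 5430419D17Rik at -6.94, 9530053A07Rik at -6.73, the noncoding RNA BB123696 at -6.56, 9530002B09Rik at -6.53, Sbp (spermine-binding protein, a prostate secretion) at -6.28, Spink5 at -5.98 and the defensin Defb50 at -5.70 on the log2 scale. Their order depends on the libraries: 9530053A07Rik had 8.11 and 36.3 CPM in the intact total RNA libraries, and without replicate 2 of them it was at -5.26 with an adjusted p of 0.19, Sbp at -5.52 and Defb50 at -5.08. Without castrate total RNA replicate 2, 9530002B09Rik was at -5.82, and without castrate total RNA replicate 1, 5430419D17Rik was at -7.81 and BB123696 at -7.27. Probasin (Pbsn), whose promoter drives the Cre, had no counts in any of the 3 castrate total RNA libraries against 10 and 27 in intact ones, so it was at least 19.7-fold lower against the floor. The largest rise among such genes was Cacna2d3, a calcium channel subunit, from 0.37 ± 0.21 to 16.8 ± 5.56 CPM, a log2 fold change of 5.34 ± 0.66 (SE). The serine protease Tmprss11b rose by 4.99 and the platelet chemokine Ppbp by 4.59 on that scale. The other largest rises among them were small or noncoding RNAs: Snora30 at 5.27, Snora65 at 5.07, the noncoding Tbrg3 at 4.90, Snora81 at 4.75 and Snord61 at 4.56. These lie within the spans of Srcap, Rpl12, Tcf20, Eif4a2 and Rbmx, so their counts are uncertain. With 1 library left out Tmprss11b ran from 3.99 to 8.998, Ppbp from 3.84 to 7.02, Cacna2d3 from 4.93 to 6.06 and Snora30 from 4.63 to 6.79, each highest without intact total RNA replicate 2. Snora65 ran from 4.59 to 5.99, Tbrg3 from 4.53 to 5.41, Snora81 from 4.11 to 5.33 and Snord61 from 3.96 to 5.32. Of 40 called genes named for total RNA, 8 passed with each library left out in turn: Spink1, Spink5, Sbp, Defb50, Fkbp5, BB123696, 5430419D17Rik and 9530002B09Rik. Of 94 measured snoRNA genes 19 passed and 88 had a positive log2 value, with a median of 1.85. Summed snoRNA counts were 3168 CPM in castrate total RNA replicate 2, 10308 and 9689 CPM in replicates 1 and 3, and 1746 and 2186 CPM in intact total RNA.

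Epithelial markers moved in both directions in total RNA. The luminal list had 2 of 14 members lower: the prostate homeobox gene Hoxb13 at -1.74 and the tight junction gene Cldn3 at -1.10. It passed camera (adjusted p 0.00241, and adjusted p = 0.59 with an estimated correlation), with 3 lower adjusted over the list alone. The luminal progenitor list, markers described in castration-resistant luminal cells, had 3 of 13 higher: Ly6d at 1.47, Gsdmc2 at 1.45 and Krt4 at 1.28. Its camera adjusted p was 0.0448, or p = 0.85 with an estimated correlation and 0.0582 without castrate pair 3, and 4 were higher adjusted over the list alone. The neutrophil list had 3 of 10 members higher, Retnlg at 3.46, S100a9 at 2.49 and S100a8 at 1.79, and all 10 were positive. Its camera adjusted p was 5.99e-06, or adjusted p = 0.57 with an estimated correlation, with 5 higher adjusted over the list alone. With 1 library left out Retnlg ran from 2.93 to 4.13, S100a9 from 1.75 to 2.76 and S100a8 from 1.48 to 2.04. S100a9 and S100a8 were lowest without castrate total RNA replicate 2. The 3 genes lost their calls in 5, 6 and 7 of these fits.

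The lymphocyte list had 14 of 14 positive members, none of which passed, with a median log2 value of 1.80. Castrate total RNA replicate 2 carried much of this: lymphocyte genes summed to 986.0 CPM in it, against 439.2 and 380.5 CPM in the other castrate total RNA libraries and 311.1 and 226.4 CPM in intact ones. Without it the median was 0.85 and the camera adjusted p 0.0354. The adipocyte list had 10 of 10 positive members and a median of 1.97, none past the threshold over all genes and 8 higher adjusted over the list alone. The camera adjusted p-values of the lymphocyte and adipocyte lists were 0.000762 and 4.22e-05, or p = 0.63 and p = 0.58 with an estimated correlation. Skeletal muscle genes summed to 4564 CPM in castrate total RNA replicate 3, against 64.1 and 163.9 CPM in the other castrate total RNA libraries and 140.9 and 146.8 CPM in intact ones. Adipocyte genes summed to 889.8 CPM in that library, 616.7 and 188.9 CPM in the other castrate ones and 158.6 and 86.8 CPM in intact ones.

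Nuclear-encoded respiratory chain genes had 6 of 56 members higher in castrate total RNA, and 16 higher and 1 lower adjusted over the list alone. Ndufa5 rose by 1.65, Ndufa4 by 1.12, Ndufs1 by 0.88 and Sdhb by 0.85 on the log2 scale. The camera adjusted p was 5.99e-06, or p = 0.58 with an estimated correlation. The cholesterol synthesis list had 1 of 19 lower, the sterol regulator Insig1 at -1.05 (camera adjusted p 0.0224, or p = 0.85 with an estimated correlation). The list of mRNAs with regulated upstream reading frames had 1 of 13 lower, the stress transcription factor Atf5 at -1.01 (camera adjusted p 0.0448, or p = 0.58 with an estimated correlation and 0.11 without castrate pair 3). Macrophage and immediate early lists also passed camera, each at an adjusted p of 0.0448, with 0 members past the threshold in either, and p = 0.85 and p = 0.58 with an estimated correlation. With each library left out in turn, the gene call was lost in 2 fits each for Ndufa5 and Ndufa4. It was lost in 4 for Ndufs1, 8 for Sdhb, 7 for Insig1 and 9 for Atf5. Leaving out 1 library ended the camera call of 5 lists in total RNA. The highest adjusted p was 0.35 for luminal progenitor genes, without intact total RNA replicate 1, and 0.14 for immediate early genes, without castrate total RNA replicate 2. It was 0.29, 0.21 and 0.98 for the cholesterol, upstream reading frame and macrophage lists, without intact total RNA replicate 2.

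Among the genes the study followed, Klf5, a transcription factor (chromosome 14, 99298691 to 99313412), fell from 290.0 ± 9.49 to 115 ± 48.2 CPM, a log2 fold change of -1.34 ± 0.29 (SE) with an edgeR adjusted p of 0.0345. Eif4ebp1, which encodes the translation repressor 4EBP1 (chromosome 8, 27260327 to 27275656), fell from 23.9 ± 1.89 to 11.05 ± 1.78 CPM, a log2 fold change of -1.12 ± 0.27 with an edgeR adjusted p of 0.0455. With each of the 10 libraries left out in turn, Klf5 ran from -1.71 to -1.09 and lost its call in 6 fits. Eif4ebp1 ran from -1.23 to -1.01 and lost its call in 9, so neither call is firm. Denr and Cacul1 had log2 values of -0.46 and -0.44 and did not pass, with edgeR adjusted p-values of 0.17 and 0.33. The list of Klf5, Denr and Cacul1 passed camera (adjusted p 0.0118, or p = 0.37 with an estimated correlation), and the study chose it on these samples. The androgen receptor gene Ar had a log2 value of 0.05 ± 0.21 (SE) and did not pass. The number of calls rested on few libraries: without intact total RNA replicate 2 it was 3 higher and 14 lower, without intact total RNA replicate 1 it was 8 and 33, and without castrate total RNA replicate 1 it was 71 and 53. Without castrate protected replicate 1 it was 124 and 171, without intact protected replicate 1 157 higher and without intact protected replicate 2 152 higher. With total RNA libraries alone in the fit it was 20 and 32, with DESeq2 612 and 546, and without castrate pair 3 in both fractions 418 and 368.

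**Figure D2:**
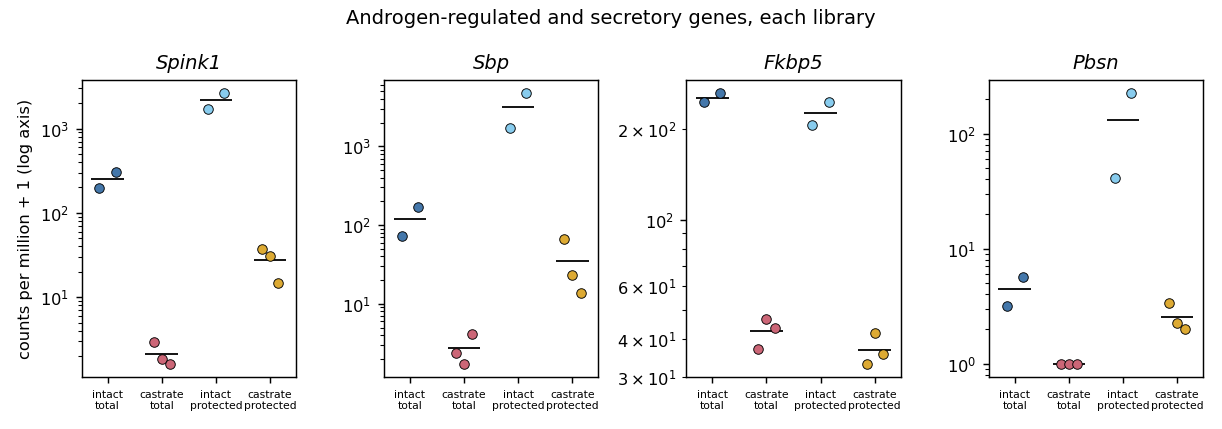
Points are the CPM plus 1 of each library on a log axis, and the line is the group mean, for Spink1, Sbp, Fkbp5 and Pbsn in 4 groups of 2 or 3 libraries. Castrate libraries lie below all intact libraries of the same fraction for the 4 genes, with Fkbp5 at 41.6 against 253 CPM in total RNA.

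The comparison of protected RNA asked how castration changed the RNA held by ribosomes. Prostate secretions again fell. The 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between libraries were these. Msmb (microseminoprotein) had a log2 fold change of -7.01 ± 1.12 (SE), Tgm4 (prostate transglutaminase) -6.75 ± 0.89, 9530002B09Rik -6.74, Sbp -6.57, Pbsn -6.37, Spink1 -6.32, Defb50 -6.19 and 5430419D17Rik -6.01. In the intact protected libraries Msmb was at 6.63 and 81.5 CPM, Tgm4 at 22.4 and 96.5 CPM and Pbsn at 39.8 and 222 CPM. Without replicate 2 of them their log2 values were -4.29, -5.35 and -4.65 and none of the 3 passed, while Sbp was at -5.65, Defb50 at -4.92 and 5430419D17Rik at -5.35 and these passed. Fkbp5 fell from 225 ± 27.4 CPM (SD, n = 2) to 36.0 ± 4.61 CPM (SD, n = 3). The androgen list had 15 of 35 members lower and 1 higher, and 16 lower and 2 higher adjusted over the list alone. The higher member was Sord, a sorbitol dehydrogenase, at 1.60, named after its value was seen. The camera adjusted p was 1.16e-23, or p = 0.086 with an estimated correlation.

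The fit of all 10 libraries called 234 genes by edgeR in castrate protected RNA. With protected libraries alone 219 were called, 163 of them shared. Of the 234 genes, 90 were higher and 144 lower in castrate. The largest rises under the same conditions were Ppbp at 5.30 ± 0.88 (SE), the serine proteases Tmprss11g at 5.24 and Tmprss11b at 5.07, Cacna2d3 at 4.96, Coch at 4.34, Retn at 4.04, Krt13 (a keratin of stratified epithelium) at 3.60 and the membrane mucin Muc13 at 3.58. With 1 library left out Ppbp ran from 4.79 to 5.96, Tmprss11g from 4.59 to 6.28, Tmprss11b from 4.30 to 7.20, Coch from 3.75 to 5.50 and Retn from 3.39 to 5.09, in each case between the omission of one intact protected library and of the other. Of 28 called genes named for protected RNA, 6 passed with each library left out in turn: Spink1, Sbp, Defb50, Fkbp5, 5430419D17Rik and 9530002B09Rik. Basal epithelial markers had 3 of 14 members higher and 6 higher adjusted over the list alone. They were Krt5, from 625 ± 6.81 to 1627 ± 274 CPM, with Lgals7 at 1.45 and the desmosomal gene Dsc3 at 1.62 on the log2 scale. The camera adjusted p was 3.61e-05, or p = 0.095 with an estimated correlation. In the neutrophil list Cxcr2 and S100a8, both at 1.93, were higher and all 10 members were positive (camera adjusted p 5.08e-06, or p = 0.47 with an estimated correlation).

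The adipocyte list had 10 of 10 positive members, with Retn higher and a median log2 value of 2.81, and 8 higher adjusted over the list alone. Its camera adjusted p was 2.62e-08, or p = 0.47 with an estimated correlation. Adipocyte genes summed to 2105, 539.9 and 1934 CPM in castrate protected libraries and 403.8 and 171.1 CPM in intact ones. Skeletal muscle genes summed to 11734 CPM in castrate protected replicate 3, against 179.2 and 513.0 CPM in the other castrate protected libraries and 418.3 and 380.8 CPM in intact ones. Lymphocyte (14 of 14 positive, camera adjusted p 0.00169), macrophage (0.0359), luminal (0.0198) and fatty acid synthesis (0.0228) lists passed camera with 0 members past the threshold over all genes, and p = 0.77, p = 0.85, p = 0.77 and p = 0.77 with an estimated correlation. The histone list had 1 of 20 lower, Hist1h2be at -1.18, and the noncoding RNA list had 0 of 20 (camera adjusted p-values 0.0252 and 0.0198, or p = 0.77 for each with an estimated correlation, and 0.42 and 0.11 without castrate pair 3). Lymphocyte genes summed to 1181, 1961 and 1593 CPM in castrate protected libraries and 962.2 and 822.0 CPM in intact ones, and without castrate protected replicate 2 the list had a median of 0.41, down from 0.99, and an adjusted p of 0.0874. Leaving out 1 library also ended the calls of 5 other lists. The highest adjusted p was 0.70 and 0.47 for macrophage and luminal genes without intact protected replicate 2, 0.23 and 0.24 for fatty acid synthesis and noncoding RNA genes without intact protected replicate 1, and 0.41 for histones without castrate protected replicate 3.

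Klf5 was at 309 ± 66.8 CPM in intact and 306 ± 37.1 CPM in castrate protected RNA, a log2 value of -0.02 ± 0.30 (SE). Eif4ebp1 had a log2 value of -1.02 ± 0.28, with an edgeR adjusted p of 0.10. Pten, Ar, Denr and Cacul1 had log2 values of 0.35, 0.46, 0.31 and 0.47, and none passed. Of the genes called in each fraction 57 were higher in both, against 1.44 for independent lists, and 66 were lower in both, against 2.34. No gene was called in opposite directions. Log2 fold changes correlated across 15838 genes with a Pearson r of 0.50 and a Spearman rho of 0.46, genes not being independent replicates, and the paired libraries share their deviations. Without intact protected replicate 2 the protected calls were 1 higher and 13 lower, and without intact protected replicate 1 they were 7 and 36. Without castrate protected replicate 1, 2 or 3 they were 22 and 33, 39 and 45, or 46 and 53. Without castrate total RNA replicate 1 or 2 they were 54 and 88 or 190 and 277, and without intact total RNA replicate 1 or 2 they were 53 and 77 or 46 and 68. Without castrate pair 3 they were 78 and 94, and with DESeq2 298 and 314.

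**Figure D3:**
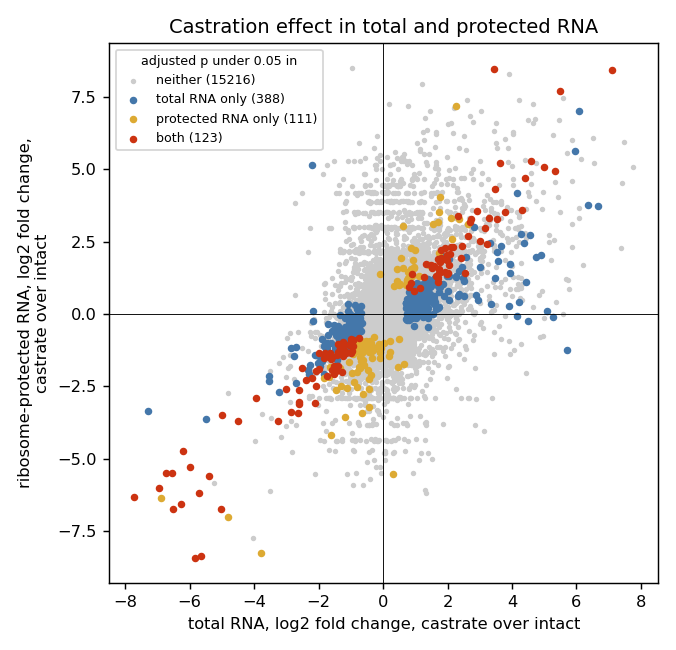
Each point is 1 of 15838 genes, with the log2 fold change of castrate over intact in total RNA (horizontal) and in protected RNA (vertical), coloured by where the edgeR adjusted p was under 0.05. Genes called in both fractions (57 higher, 66 lower) lie in the upper right and lower left quadrants.

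The central question of the study was whether castration changed translation relative to RNA level. No gene passed the interaction test of edgeR in either direction. At an unadjusted p under 0.05 there were 408 genes with higher and 600 with lower translational efficiency in castrate, and the smallest adjusted p was 0.71. With the pairs as a block the count of calls stayed 0, with a smallest adjusted p of 0.13. At an unadjusted p under 0.05 the block fit had 633 genes higher and 846 lower. Limma also called 0 genes, and DESeq2 called 3 lower, the snoRNA genes Snora30, Snora65 and Snora70, the last named after its value was seen. The genes nearest to the threshold, none of which passed, were Rbm15b at 1.71, Zfp574 at 1.23 and Chpf at 1.45 on the positive side and Snora30 at -5.39, Snora65 at -4.96 and Ctla2a at -1.64 on the negative side.

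Klf5 had a translational efficiency difference of 1.33 ± 0.42 (SE, log2), with an unadjusted p of 0.00863 and an edgeR adjusted p of 0.71. Its total RNA was lower and its protected RNA level was near equal in castrate. Denr, a factor of non-canonical initiation, had a difference of 0.77 ± 0.25 and Cacul1 of 0.91 ± 0.34, with edgeR adjusted p-values of 0.71 and 0.76. All 3 passed adjusted over the list alone, which is not independent evidence because the study chose them on these samples, and the list passed camera at 9.36e-05, or p = 0.14 with an estimated correlation. Eif4ebp1 had a difference of 0.10 ± 0.39, Pten of 0.76 ± 0.28 and Ar of 0.41 ± 0.30, and none passed. The SEs and edgeR p-values of these genes come from the fit that does not use the pairs of libraries. With the pairs as a block no gene passed either.

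**Figure D4:**
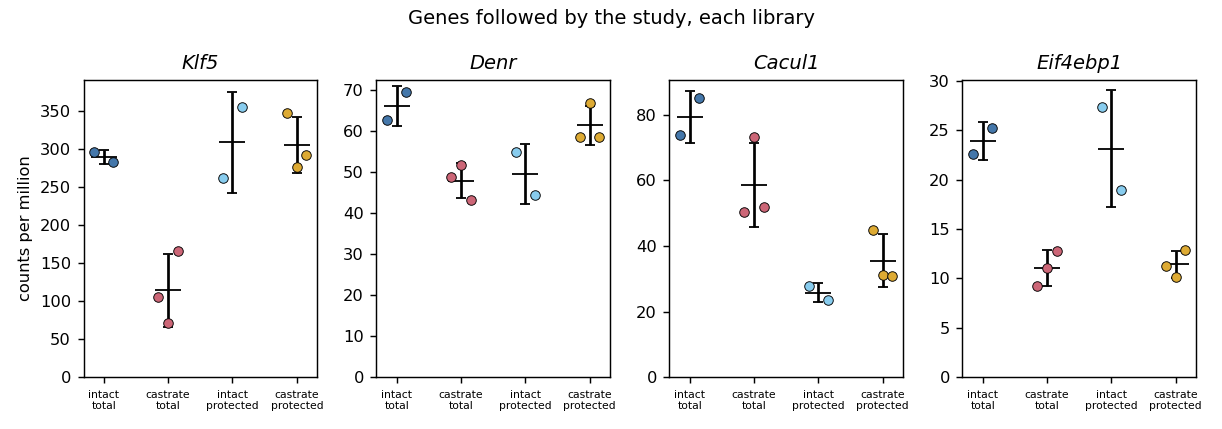
Points are the CPM of each library and bars the mean and SD of each group of 2 or 3 libraries, for Klf5, Denr, Cacul1 and Eif4ebp1. Klf5 averages 290.0 CPM in intact and 115 CPM in castrate total RNA, and 309 and 306 CPM in protected RNA.

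Ribosomal protein mRNAs, whose translation depends on mTOR, showed no call in translational efficiency among 79 measured members, with a median log2 value of -0.07 and a camera adjusted p of 0.76. Other mRNAs with the same 5-prime motif had 0 of 17 called, a median of 0.13 and a camera adjusted p of 0.24. Nuclear-encoded respiratory chain genes had 47 of 56 negative values, a median of -0.36, 0 calls over all genes and 1 lower adjusted over the list alone. Their camera adjusted p was 8.78e-07, or p = 0.62 with an estimated correlation. The histone list (median -0.65) and the noncoding RNA list (median -1.002) were lower, and the PI3K and AKT list (median 0.23, with Phlpp1 at 0.86) and the basal list (median 0.31, with Col17a1 at 0.66) were higher. Their camera adjusted p-values were 8.72e-05, 0.000676, 0.00177 and 0.0331, or p = 0.62, p = 0.60, p = 0.20 and p = 0.51 with an estimated correlation, and none of their members passed over all genes. The noncoding RNAs encode no protein, so the pass of that list cannot show a change in translation. A camera pass in this comparison is therefore not by itself evidence of such a change for the other lists. Without castrate pair 3 the noncoding RNA and basal lists no longer passed, with adjusted p-values of 0.0954 and 0.0670, and with 1 library left out the highest were 0.0579 without intact protected replicate 1 and 0.13 without intact total RNA replicate 1.

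Protected RNA was compared with total RNA within each status to show which transcripts are over- or under-represented in the protected libraries. Small RNA genes that encode no protein were among the largest ratios, so a high ratio does not by itself show translation. In intact animals 3279 genes were higher and 3193 lower in protected RNA by edgeR, and in castrate animals 3725 and 4081. With TMM set within each fraction the share of higher calls went from 50.7% to 33.6% in intact and from 47.7% to 29.9% in castrate, and the median log2 ratio of all genes went from -0.06 to -0.42 and from -0.08 to -0.44, so the direction of small ratios depends on the scaling. Atpaf1, a mitochondrial ATP synthase assembly factor, was higher in both, at 6.76 ± 1.18 (SE, log2) in intact and 5.47 ± 0.91 in castrate. In intact animals the small RNA genes Mir6481, Mir429 and Rnu11 were higher by 8.33, 5.95 and 5.81. Mir6481 had 7 and 214 counts in the intact protected libraries and was at 4.54 without replicate 2 of them. Mir429 had 132 and 29 counts there and was at 4.30 without replicate 1, and Atpaf1 was at 5.23 without that library. In castrate animals Atpaf1 was at 222, 2653 and 4057 CPM in the protected libraries, and its log2 ratio was 4.80 without replicate 3 of them. In castrate animals Pbsn, Fam227a and Spink1 were higher, at 26.9 against 1.14 CPM for Spink1. Fam227a was at 4.84, or 3.85 without castrate protected replicate 2, and Pbsn had an adjusted p of 0.0272, or up to 0.0901 without 1 of castrate total or protected replicates 1 and 2. In intact animals Oaz1, 4930546K05Rik, D830030K20Rik and Gdap10 had no counts in protected RNA and 19.9, 53.5, 35.1 and 16.5 CPM in total RNA, and D830030K20Rik had an adjusted p of 0.0520 without intact protected replicate 2. In castrate animals Snord11 and Raver1 had no counts in protected RNA, and Stk-ps2 and P2ry4 had log2 ratios of -8.32 and -6.94, which ran from -10.53 to -7.85 and from -9.14 to -6.05 with 1 library left out. Oaz1, Gdap10, 4930546K05Rik, D830030K20Rik, Mir6481, Mir429, Snord11 and Raver1 overlap other genes, so their counts are uncertain.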

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

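All tests in this part concern 6 gene lists whose protected-over-total ratio differed between castrate and intact libraries in the interaction test by camera. The adjusted p-values were 8.78e-07 for nuclear-encoded respiratory chain genes, 8.72e-05 for histones, 9.36e-05 for the genes the study followed, 0.000676 for noncoding RNA, 0.00177 for PI3K and AKT genes and 0.0331 for basal epithelial genes. None passed with an estimated correlation. Leaving out each library in turn was planned, but its use for castrate total RNA replicate 2 as a test of an explanation, and the test that sets libraries against the protected profile, were chosen only after the result was seen.

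The lower translational efficiency of respiratory chain genes came from total RNA, where their median log2 change was 0.41, while in protected RNA it was 0.01. Without castrate total RNA replicate 2 the list kept a camera adjusted p of 2.38e-05 at the preset correlation. This argues against that library as the sole source of the call at this setting. With an estimated correlation the list did not pass even with all libraries, so the p is not firm evidence. In intact animals these genes had a median log2 ratio of protected over total RNA of 1.83 (quartiles 1.16 and 2.26), so a shift of castrate total RNA libraries towards the protected profile would raise them. Such a shift was clear by correlation for replicate 2 alone: castrate total RNA replicates 1, 2 and 3 had mean correlations with intact protected libraries of 0.841, 0.870 and 0.832, against 0.835 and 0.842 for intact total RNA set against the protected library of the other number. With intact protected replicate 1 alone the castrate values were 0.851, 0.878 and 0.844, against 0.842 for intact total RNA replicate 2. With intact protected replicate 2 alone they were 0.831, 0.862 and 0.821, against 0.835 for intact total RNA replicate 1. On the first principal component all castrate total RNA libraries (-79.2, -45.5 and -76.6) lay nearer to the protected ones than intact total RNA (-91.2 and -96.8). Across 12145 genes the castration change correlated with the ratio at r = 0.42 and r = 0.29, or 0.34 and 0.20 without replicate 2. Each of these quantities subtracts an intact total RNA library, and those 2 libraries correlate at r = 0.98. A deviation that they share would give a positive r without any shift, so this r cannot decide. Both a shift and an effect of castration on these mRNAs stay open, and whether differences in tissue make-up between libraries contributed was not tested. The respiratory chain genes summed to 4273, 4870 and 4956 CPM in castrate total RNA replicates 1, 2 and 3. In intact total RNA they summed to 3741 and 3801 CPM.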

How the results depend on the processing

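Leaving out either intact total RNA library lowered both counts of total RNA by more than 1.5 times, and leaving out either intact protected library did so for both counts of protected RNA. No setting varied depth. Limma on log2(CPM + 1), protein-coding genes only, TMM within each fraction and omission of castrate pair 3 were chosen after seeing the data. For total RNA the counts of 254 higher and 257 lower became 20 and 32 with total RNA libraries alone, 90 and 68 with limma without a trend, 612 and 546 with DESeq2, and 418 higher without castrate pair 3, and the lower count became 161 with limma after quantile scaling, against 228 with limma on log2(CPM + 1). For protected RNA the counts of 90 and 144 became 172 and 227 without a filter, 298 and 314 with DESeq2, and 157 and 222 with limma after quantile scaling, against 167 and 207 with limma on log2(CPM + 1). The higher count became 174 and 151 with limma at pseudocounts of 0.25 and 4, and the lower count became 94 without castrate pair 3. Leaving out 1 library at a time gave 3 to 360 higher and 14 to 305 lower in total RNA, and 1 to 190 higher and 13 to 277 lower in protected RNA. It gave 2059 to 3504 lower in protected against total RNA of intact animals. Where 1 library of a group was left, it was assumed to vary like the other groups. Translational efficiency stayed at 0 calls in each setting except DESeq2, with 3 lower. TMM within each fraction gave 2384 higher in protected against total RNA of castrate animals. The cause was not tested for any of these, except that fewer libraries entered the fits that left some out.

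With an estimated correlation 0 lists passed in each of the 3 comparisons, against 12, 10 and 6 with the preset one, and the lists past the threshold for translational efficiency numbered 5 to 13 when 1 library was left out. Castrate and intact libraries share only a number across statuses (correlations of deviations from -0.08 to 0.08), and the replicate block gave 65 higher and 74 lower in total RNA and 271 higher in protected RNA. These fits held only the libraries of the fraction tested. Replicate 3 has no intact library, so castrate replicate 3 added nothing to the castration difference in them. The counts therefore do not show the effect of the block alone. With total and protected libraries paired in a replicate block, translational efficiency had 0 calls and 6 lists, and protected against total RNA changed by less than 1.5 times. Named genes that changed sign were below the threshold in each such setting. Klf5 in protected RNA was at 0.022 with the replicate block and 0.013 without castrate pair 3, and from -0.23 to 0.22 when 1 library was left out. Ar in total RNA ran from -0.0883 to 0.21 and the translational efficiency of Eif4ebp1 from -0.13 to 0.40 when 1 library was left out. Of the values of named genes under the alternatives, 806 of 1050 in total RNA, 709 of 816 in protected RNA and 337 of 342 in translational efficiency kept their direction and side of the threshold. A further 243 and 102 in total and protected RNA no longer passed, and 3 in translational efficiency passed with DESeq2. The test on reads recovered from CPM was not needed, because the files hold counts.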

Other observations

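Cell cycle genes had 0 of 37 called by edgeR in total RNA, with a median log2 change of 0.14, and neuroendocrine markers 0 of 13, with a median of 0.15. Interferon response genes had 0 of 26 called and MHC genes 0 of 15. Fibroblast, smooth muscle and endothelial markers had 0 of 19, 0 of 14 and 0 of 13 called in total RNA, with medians of -0.22, 0.10 and -0.04. Ribosomal protein genes had 1 of 79 called higher (Rps27l), other mRNAs of their class 0 of 17, initiation factors 2 of 32 lower (Eif4ebp1 and Mknk2), ATF4 targets 0 of 20, unfolded protein response genes 1 of 20 lower (Sdf2l1), fatty acid synthesis genes 0 of 10 and eIF4-sensitive oncogenes 0 of 16. The mTOR-sensitive invasion list had 0 of 4 called and the mesenchymal list 0 of 13. Histone, noncoding RNA, PI3K and skeletal muscle lists had 0 of 20, 0 of 20, 0 of 21 and 0 of 12 called in total RNA. The basal list had 3 of 14 higher in total RNA (Dsc3, Krt14 and Krt5) and a camera adjusted p of 0.15. Seminal vesicle and red blood cell lists had 1 measured gene each, too few to test, and the mitochondrially encoded list had 0. In protected RNA Aqp3 and Krt4 of the luminal progenitor list and Tgfb2 of the mesenchymal list were higher, and Sec61b of the unfolded protein response list was lower.

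The tests of muscle, fat and small RNA were chosen only after the result was seen. The skeletal muscle list had a median log2 change of 3.57 in total RNA, and -0.086 without castrate pair 3, which is consistent with muscle carried in with that pair. Adipocyte genes behaved otherwise: without that pair their list in protected RNA kept an adjusted p of 2.19e-07, which argues against fat from that pair alone. Fat around the other castrate glands, and a change within the gland, both stay open, since no value here decides between them.

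Over 94 measured snoRNA genes the median log2 value in total RNA was 1.85 (quartiles 0.84 and 2.82), 88 were positive and 19 passed, and snoRNA genes as a group were not tested. Summed snoRNA counts were 10308, 3168 and 9689 CPM in castrate total RNA and 1746 and 2186 CPM in intact total RNA. Small RNA genes of other classes (snRNA, guide RNA, RNase P, RNase MRP and telomerase RNA) had 17 of 18 positive values and a median of 1.51 (quartiles 0.86 and 1.75), with 0 called. All small RNA classes together took 4.51%, 1.62% and 6.33% of castrate total RNA counts and 1.54% and 1.61% of intact ones, so replicate 2 was close to the intact libraries in this share and nearer to them than to replicates 1 and 3 in summed snoRNA counts. In protected libraries this share was 0.58%, 3.65% and 0.81% in castrate and 4.59% and 2.94% in intact. The rise of the share in castrate total RNA was therefore not shared by the protected fraction. A higher content of small RNA in the library preparation and a change in the tissue both stay open.

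The 6 castrate libraries can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The division into protected and total RNA called 7806 genes, 1 of the 10 divisions gave as many, and the highest of the others called 0.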
